A study of Caenorhabditis elegans with 4 samples.

How the data were processed

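Chromatin immunoprecipitation followed by sequencing was carried out on mixed-stage embryos of the wild-type *Caenorhabditis elegans* strain N2, grown at 20 °C. Embryos were released from gravid adults by bleaching, fixed with 2% formaldehyde for 30 min and sonicated, per the labels' protocols. Each precipitation started from 2 mg of extract with 1% sarkosyl, and 10% was set aside as input. The antibody was an affinity-purified rabbit polyclonal raised against AMA-1, the large subunit of RNA polymerase II. The labels name 4 samples: 2 ChIP samples and 2 inputs, each group numbered as replicates 1 and 2. The labels do not say whether the replicates came from separate cultures, so the spread between them may be technical.

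The analysis used 3 peak lists: 1 for each ChIP replicate and 1 for the series as a whole. No values of the input samples were analysed here. Reads were aligned with BWA to ce10, per the submitters' processing notes. The build is WormBase WS220 in all 3 lists, per the file headers, and ce10 is the UCSC name of that assembly. The source column of the replicate lists names MACS and that of the series-level list names MACS v2, per the file headers and columns. The thresholds, the control used and the way the series-level list was made from the samples are not given in the sources used here.

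Each peak has a start, an end and a score, which is the authors' own value from their peak caller; no header or label gives its scale. The deposited score starts at 50.03 in replicate 1, 50.07 in replicate 2 and 1.30 in the series-level list. In the replicate lists it reaches a ceiling: 101 peaks of replicate 1 and 368 of replicate 2 have exactly 3100, with 9 and 25 peaks above it. Score levels were therefore compared only between peaks of the same list, as medians or ranks, and between lists only as a correlation. Ranks are given as percentiles, from 0 for the weakest to 100 for the strongest peak, with ties averaged. Read depth is unknown, so no interval rests on reads.

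Peaks were compared by overlap of at least 1 bp. Chance was set by sliding one list around each chromosome by a random distance, which keeps the number, width and spacing of its peaks. Each main overlap test used 100000 such shifts and was one-sided, and comparisons by score quartile or with the series-level list used 1000 shifts. Median scores and widths were compared by two-sided permutation tests with 100000 resamples. Since wider peaks overlap more by chance, the differences between shared and unshared peaks were also set against 1000 shifts, a comparison chosen after the values were seen. Agreement of scores was measured at pairs in which each peak overlapped exactly 1 peak of the other list. Peaks are not independent replicates, so these p-values describe the 2 lists. Benjamini-Hochberg adjustment was applied over the 8 main tests.

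Densities were expressed as peaks per Mb of chromosome, with the position of a peak taken at its midpoint. Since no genome of this build was used, the length of a chromosome was taken as the highest peak end over the 3 lists, 100.2 Mb in total. Intervals of densities are exact Poisson intervals, those of density ratios exact conditional binomial intervals, and those of shares Wilson intervals, all at 95%. They cover counting error only, and neighbouring peaks are not independent. The centre of a chromosome was the part from 33.3% to 66.7% of its length and the arms were the rest. Centres and arms were compared over the 6 chromosomes by an exact two-sided sign-flip permutation test on log2 ratios, whose smallest possible p is 0.03125. X was set against the 5 autosomes without a p-value across chromosomes.

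The regions named were fixed by a rule before the data were examined: the 10 series-level peaks found in both replicates with the highest mean replicate percentile (ties by mean width, then position), and the 5 windows of 100 kb with most bases covered in both replicates. Gene-level comparisons were also planned, on location of peaks in genes, occupied genes, gene lists and non-coding gene classes. They were not run, because the gene table at hand belongs to assembly WBcel235 and coordinates of different builds were not mixed. No gene is therefore named for any region.

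The overlap test was checked on simulated lists. Of 40 lists of 2672 peaks placed at random, 7.5% passed a threshold of 0.05. These lists did not keep the spacing of the real peaks and were tested with fewer shifts than the main lists. When peaks were planted on replicate 2 peaks, 65.8% overlap was found where 65.5% was predicted. That checks the counting of overlaps only, since no shifts were run on the planted list. Alternatives covered the overlap rule, score thresholds, equal list lengths, merging of peaks closer than 500 bp and the definition of centres and arms. They also used covered bases in place of peak numbers, each replicate alone, and the series-level list. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9 were used.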

Results

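AMA-1 is the catalytic large subunit of RNA polymerase II, the enzyme that transcribes protein-coding genes, and its ChIP signal marks DNA on which the polymerase was engaged or bound. The series profiled AMA-1 in mixed-stage wild-type embryos, with 2 ChIP samples and 2 input samples. The 2 ChIP peak lists and the series-level peak list were compared here, in WS220 coordinates. Replicate 1 held 2672 peaks that covered 11.3 Mb, or 11.3% of the 100.2 Mb spanned by peaks. Replicate 2 held 3818 peaks that covered 17.5 Mb, or 17.4%. Peaks were broad in both replicates, with a median width of 3286.5 bp in replicate 1 (quartiles 2149.5 and 5262 bp) and 3311 bp in replicate 2 (quartiles 2106 and 5796 bp). The series-level list held 18518 peaks with a median width of 406 bp, and these covered 13.4 Mb. Read depth behind the lists is unknown.

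The first question was whether the replicates placed the polymerase at the same sites. Of the 2672 peaks of replicate 1, 2320 overlapped a peak of replicate 2, a share of 86.8% (95% Wilson interval 85.5 to 88.1). Lists shifted along the chromosomes gave 30.8% on average. Of the 3818 peaks of replicate 2, 2010 overlapped a peak of replicate 1, a share of 52.6% (51.1 to 54.2) against 21.5% by chance. Both overlaps exceeded all 100000 shifts (one-sided permutation test, p = 1e-05, the smallest that number allows, and 1.6e-05 after adjustment over 8 tests). The bases covered in both replicates came to 9.46 Mb, which was 83.8% of the replicate 1 bases and 54.1% of the replicate 2 bases. At a finer scale the agreement was lower, since 25.8% of replicate 1 peaks and 18.1% of replicate 2 peaks had a midpoint within 200 bp of one in the other list, against 1.64% and 1.15% by chance.

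Shared peaks scored higher than unshared ones in both replicates, by more than chance overlap gave. In replicate 1 the shared peaks had a median score of 237.2 and the 352 unshared peaks 126.7 (two-sided permutation test, p = 4e-05, adjusted p = 5.3e-05). In replicate 2 the medians were 952.9 for shared and 169.6 for the 1808 unshared peaks (same permutation test, p = 1e-05, adjusted p = 1.6e-05). Shared peaks of replicate 2 were also wider, with a median of 5084 bp against 2253.5 bp (permutation p = 1e-05), and in replicate 1 the widths were 3332 and 2872 bp (p = 0.0056). These tests take no difference as their reference, but wider peaks overlap more by chance and score tracks width. Shifted lists gave a score difference of 68.2 on average in replicate 1, against 110.6 observed, and 7 of 1000 shifts gave as much (one-sided permutation p = 0.008). In replicate 2 they gave 181.3 on average against 783.3, and 0 of 1000 gave as much (p = 0.001, the smallest possible for this number of shifts; permutation test). The width difference exceeded that of shifted lists in replicate 2, 2830.5 against 968.1 bp on average, and did not in replicate 1, 460 against 678.3 bp. The share of replicate 2 peaks found in replicate 1 was 91.2% in the top score quartile, 67.6% in the next, 32.98% in the one after and 18.8% (Wilson interval 16.413 to 21.4) in the lowest. Shifts of that lowest quartile alone gave 17.4% on average and 21.6% at most, so an overlap above chance was not detectable there. In replicate 1 the lowest quartile was found in replicate 2 at 80.1%, against 26.2% by chance, and the highest at 92.8%, against 37.02%.

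**Figure D1:**
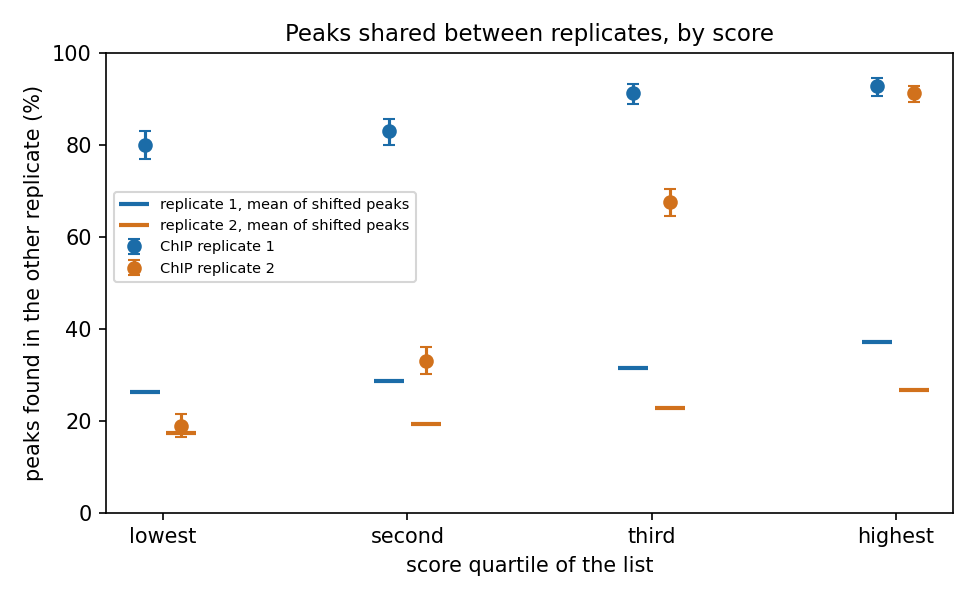
Percent of peaks of each ChIP replicate that overlap a peak of the other by at least 1 bp (y axis), by score quartile (x axis); points are shares with 95% Wilson intervals and dashes the mean of 1000 shifts of the same peaks. Replicate 1 stays at 80.1% or more throughout, while replicate 2 ranges from 18.8%, near its dash at 17.4%, to 91.2%.

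The 1663 sites with exactly 1 peak in each list were ranked alike but not identically. Across these sites the scores had a Spearman rho of 0.66 and a Pearson r of 0.63 on the log10 scale (permutation p = 1e-05 for each, adjusted p = 1.6e-05). Sites are not independent replicates. Leaving out pairs with a score at the ceiling, which left 1357, gave a rho of 0.50. The replicate 2 peak was the wider one at 1287 of the 1663 sites (77.4%, Wilson interval 75.3 to 79.3), with a median ratio of widths of 1.15.

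The 10 series-level peaks with the highest mean rank over the replicates overlapped 2 broad replicate domains, with 3 of the peaks on V and 7 on III. Each peak takes the rank of the replicate peaks it overlaps, so the grouping into few domains follows from the rule. Peaks of 1 domain tie, and those named on III are the first by position. Their own series-level scores did not enter the ranking. Both domains had the ceiling score of 3100 in replicate 2, shared by 368 peaks, so their place ahead of other ceiling domains rests on replicate 1 alone. The V domain ran from 9542443 to 9549347 in replicate 1 and from 9543224 to 9549355 in replicate 2, and had the highest score of replicate 1, 3233.06. Its main series-level peak, at 9544796 to 9548651, had a score of 115.93, at percentile 99.5 of that list. The narrower peak before it, at 9544059 to 9544517, scored 37.11 and the one after it, at 9548805 to 9549065, scored 2.58. The III domain ran from 9047437 to 9065371 in replicate 1 and from 9042356 to 9065576 in replicate 2, and held 11 and 13 series-level peaks. The broadest of the named ones there, at 9046959 to 9056557, spanned 9599 bp and scored 76.21. Further along the same ranking, taken after the values were seen, came domains on IV at 16167190 to 16171567, on X at 10567027 to 10577827, on V at 1803483 to 1806580 and on X at 13947527 to 13957956 in replicate 1 coordinates. Each of these overlapped a replicate 2 peak with a score of 3100 or more.

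The 5 windows of 100 kb with most shared coverage lay on I, II, III and V. The window of 100 kb with most bases covered in both replicates was on V from 11900001 to 12000000, where 42.4 kb lay in peaks of both. It held 5 peaks in each replicate and 29 in the series-level list. It was followed by windows on III from 6900001 to 7000000 with 40.8 kb, on V from 4500001 to 4600000 with 39.0 kb, on II from 11700001 to 11800000 with 38.9 kb and on I from 9100001 to 9200000 with 37.7 kb. The median window had 7.80% of its bases covered in both replicates. Of the 998 full windows, 165 had none. Across windows the covered share of the replicates had a Pearson r of 0.78 and a Spearman rho of 0.79, as a description of neighbouring and so dependent windows.

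The next comparison concerned the series-level list, which is not a further replicate. Of its 18518 peaks, 6145 (33.2%) overlapped peaks of both replicates, 6532 (35.3%) of replicate 2 only, 1144 (6.18%) of replicate 1 only and 4697 (25.4%, Wilson interval 24.7 to 25.996) of neither. The 74.6% found in at least 1 replicate compared with 23.2% on average, and 30.1% at most, when the list was shifted. Conversely, 2666 of the 2672 replicate 1 peaks and 3817 of the 3818 replicate 2 peaks held a series-level peak. No chance share was computed in this direction, and broad peaks often overlap so dense a list by chance. A replicate 1 peak held a median of 2 of them and a replicate 2 peak a median of 3, with up to 14 and 18. Median scores in the series-level list were 15.5 for peaks found in both replicates, 9.38 for replicate 1 only, 7.97 for replicate 2 only and 5.11 for neither, and the median widths were 734, 501.5, 395 and 251 bp. In the top score decile 97.8% were found in at least 1 replicate, and in the lowest decile 54.8%. Chance was not computed by decile, and wider peaks, which tend to score higher, overlap more by chance.

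**Figure D2:**
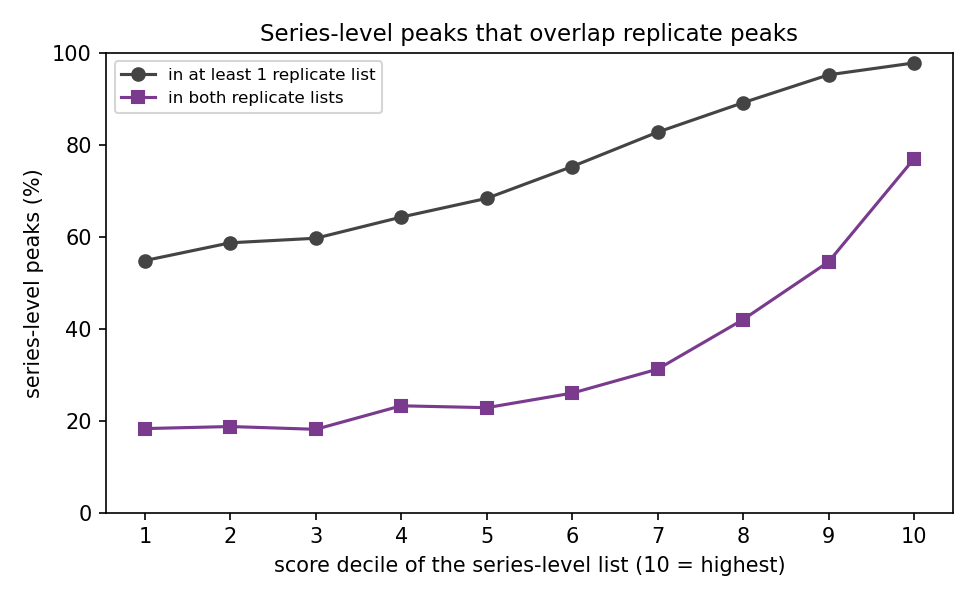
Percent of series-level peaks that overlap a peak of at least 1 replicate (circles) or of both (squares), by score decile (x axis, 10 the highest). The share in at least 1 replicate goes from 54.8% in the lowest decile to 97.8% in the highest, and the share in both from 18.3% to 77.0%.

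Polymerase peaks were unevenly spread over the chromosomes. Chromosomes I and III were densest, with 37.5 peaks per Mb (95% Poisson interval 34.5 to 40.8) and 36.4 (33.3 to 39.7) in replicate 1, and 51.9 (48.4 to 55.7) and 51.2 (47.5 to 55.1) in replicate 2. Chromosome X had 18.5 peaks per Mb (16.509 to 20.6) in replicate 1 and 28.6 (26.1 to 31.2) in replicate 2. Chromosome V was about as sparse, with 19.2 (17.4 to 21.2) and 26.6 (24.4 to 28.9). In hermaphrodites, which carry a pair of X chromosomes, dosage compensation lowers transcription from X, and the X chromosome was therefore set against the autosomes. The ratio of X to autosomal density was 0.68 ± 0.044 (SD, n = 2), with 0.649 (exact interval 0.576 to 0.729) in replicate 1 and 0.711 (0.646 to 0.781) in replicate 2. Against V alone the ratio was 0.959 (0.827 to 1.11) and 1.08 (0.951 to 1.22), so a difference between X and V as whole chromosomes was not detectable in either replicate. These ratios average parts that differ: the ratio of X to V was 0.673 (0.522 to 0.864) in centres and 1.18 (0.981 to 1.43) on arms in replicate 1, and 0.805 (0.659 to 0.983) and 1.295 (1.11 to 1.52) in replicate 2, a division chosen after the values were seen. In the series-level list X was denser than V, with a ratio of 1.21 (1.14 to 1.28), counting error only. In covered bases the ratio of X to the autosomes was 0.778 ± 0.012 (SD, n = 2). Peaks on X were wider than autosomal ones, with medians of 3947 against 3205 bp in replicate 1 and 3831 against 3245.5 bp in replicate 2 (two-sided permutation tests, p = 3e-05 and 0.00032, adjusted over 3 lists 9e-05 and 0.00048). In the series-level list the widths were 413 and 405 bp (permutation test, adjusted p = 0.45). These width tests were not among those planned, and they permute peaks, which are not independent. They describe the lists and give no p for 1 X against 5 autosomes.

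**Figure D3:**
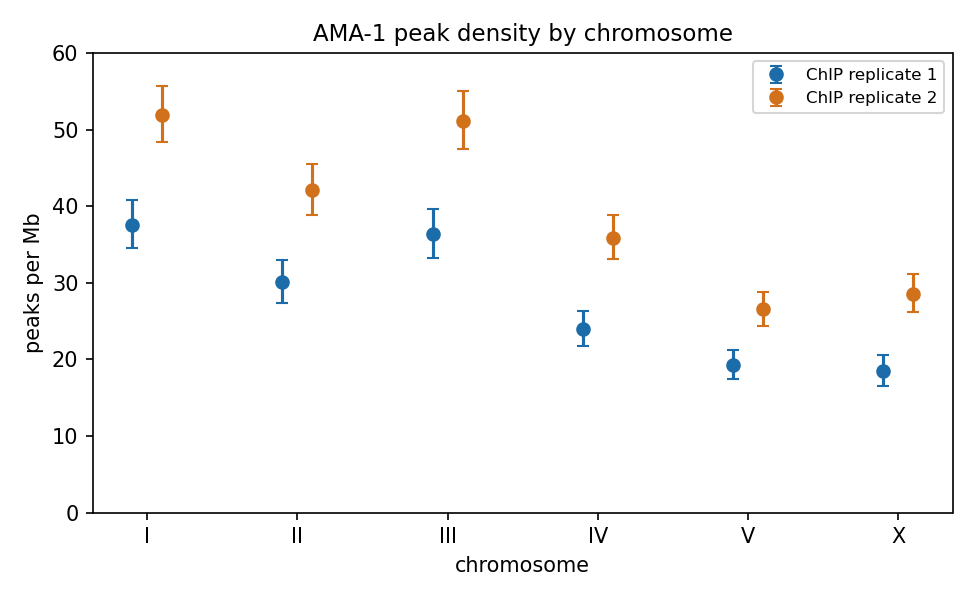
AMA-1 peaks per Mb (y axis, from 0) on each chromosome (x axis) in the 2 ChIP replicates; bars are 95% Poisson intervals. I and III are highest in both replicates at 36.4 to 51.9, and V and X lowest at 18.5 to 28.6.

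Along the chromosomes, peaks were denser in the centres of the autosomes than on their arms in both lists. The arms of *C. elegans* autosomes recombine more and are richer in repeats than the centres. On V the centre had 25.4 peaks per Mb and the arms 16.15 in replicate 1, a ratio of 1.57 (exact interval 1.28 to 1.92), and 35.7 against 21.96 in replicate 2, a ratio of 1.63 (1.37 to 1.93). On I the intervals of the ratio included 1 in both replicates, and on IV in replicate 1. On II the ratios were 1.29 (1.06 to 1.56) and 1.28 (1.09 to 1.50). Chromosome X had ratios of 0.894 (0.700 to 1.14) and 1.01 (0.836 to 1.22), and both intervals include 1. Over the 6 chromosomes the mean log2 ratio was 0.25 in replicate 1, with 5 of 6 chromosomes denser in the centre (exact sign-flip permutation test, p = 0.09375, adjusted 0.094). In replicate 2 it was 0.31, with 6 of 6 (exact p = 0.03125, adjusted 0.036 over all 8 tests and 0.0625 over these 2). The mean of both lists was 0.28, a ratio of 1.22 ± 0.036 (SD between replicates, n = 2), with an exact p of 0.0625. The contrast over all chromosomes thus did not pass 0.05 in replicate 1 or in the mean, and in replicate 2 the call depended on the set of tests adjusted over.

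**Figure D4:**
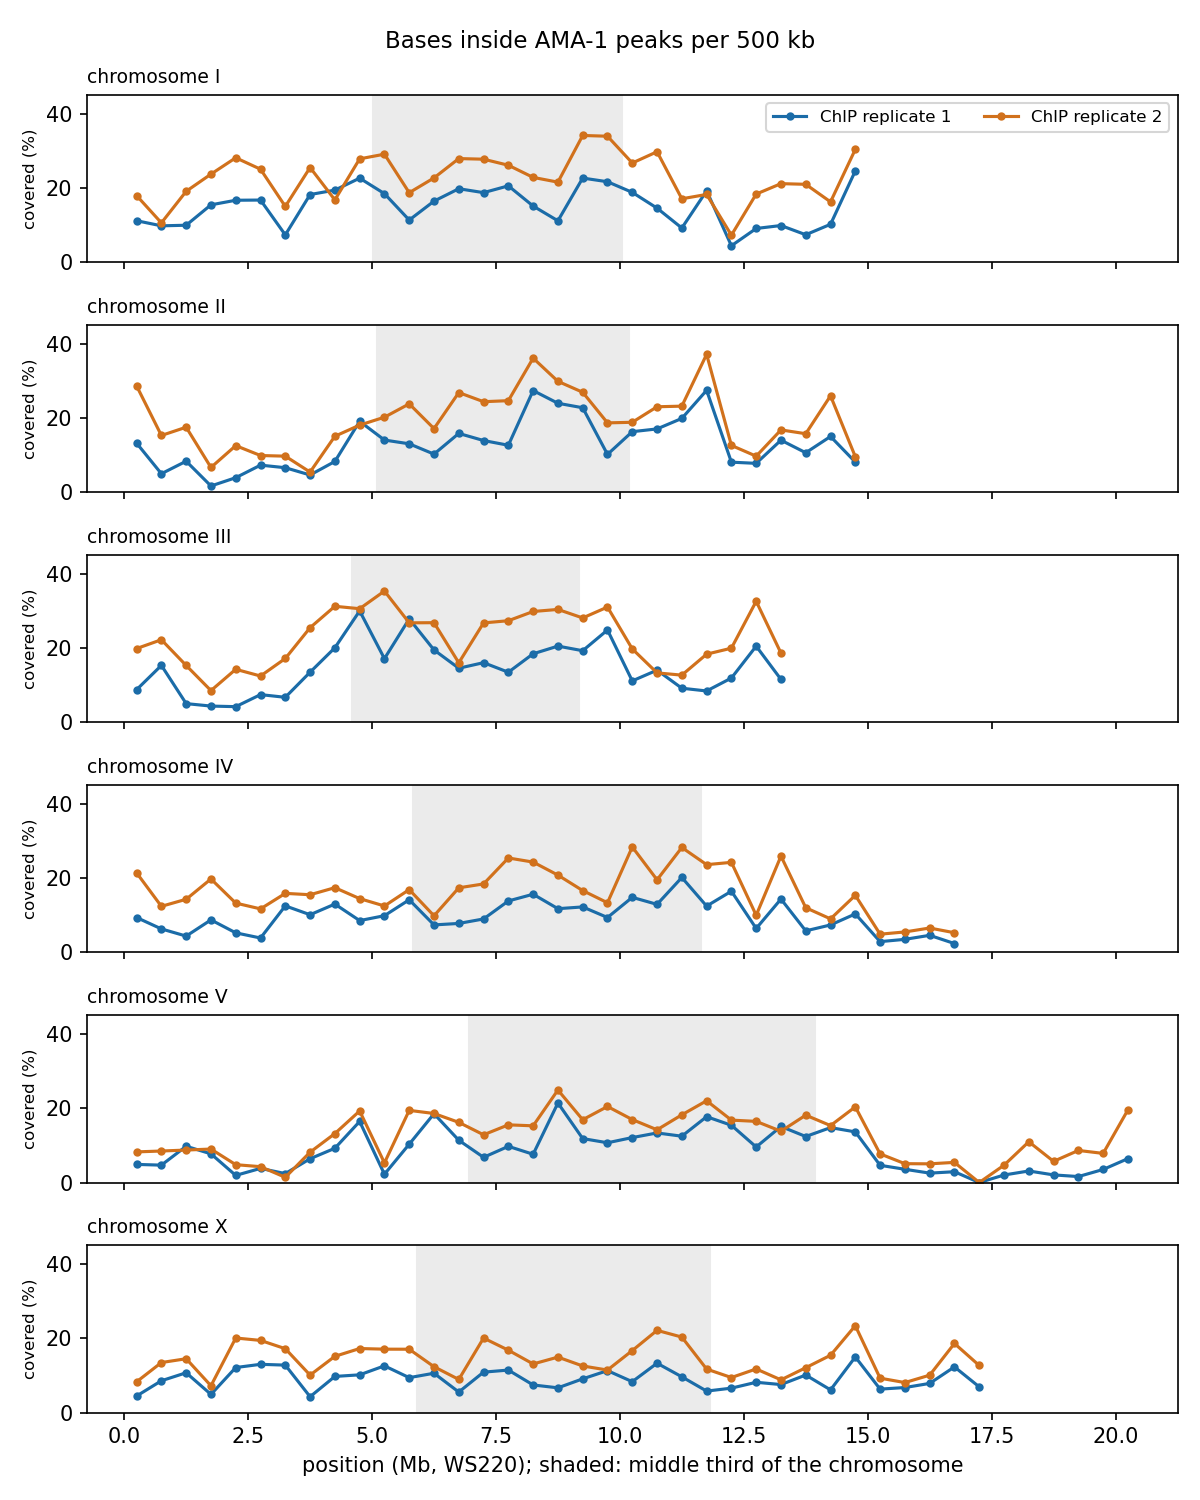
Percent of bases inside AMA-1 peaks (y axis) in full bins of 500 kb along each chromosome (x axis, Mb in WS220) for the 2 ChIP replicates; the grey band is the central part of the chromosome used for centres. Both lines are at 0 on V between 17000001 and 17500000.

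Long stretches free of peaks lay on chromosome arms, mostly of V. These were chosen after their values were seen. Of the 5 longest stretches with no peak in either replicate, 4 were on V and 1 on IV, and all 5 had their midpoint outside the chromosome centre. Arms as defined here are the larger part of each chromosome, and no chance value was computed for these positions. The longest ran on V from 16818546 to 17516342, 697.8 kb, and held 18 series-level peaks. The one on IV ran from 15051502 to 15472687, 421.2 kb, and held 6. On V, 63 of 208 windows of 100 kb (30.3%) had no bases covered in both replicates, against 12.9% of windows on the other chromosomes. In the replicate lists V thus held both the window with most shared coverage and the longest stretch without peaks. In the series-level list the longest such stretch was on IV, 394.2 kb against 386.3 kb on V.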

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

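Of 36 alternative values, 23 kept the direction and the side of the threshold, or stayed within the replicate spread, and none reversed. Some of these 23 were fixed in advance. The X ratio of each replicate alone always lies within the spread of the 2 replicates. The score differences of each list alone are parts of the main mean. The limited shifts, the X ratios by part of the chromosome or without V, the autosomes alone, the shortened series-level list and the pairs below the ceiling were chosen after seeing the data. Replicate overlap exceeded chance under all 6 alternatives in each direction, including shifts of 10 to 50 kb only, which raised chance to 33.9% and 23.4%. The percent itself ranged from 25.8 (midpoints) to 87.8 (merged) for replicate 1 peaks and from 18.1 (midpoints) to 66.8 (equal lengths) for replicate 2 peaks. The higher scores of shared peaks, a mean difference in median percentile of 29.7, held with the stricter overlap rule. The 2 lists taken singly gave 18.7 and 40.8, which are the parts of that mean, since sharing is always defined by both lists. Widths in place of scores gave 24.4, and in replicate 1 the width difference was within that of shifted lists. The share of series-level peaks found in at least 1 replicate, 74.6%, was 88.1% for the peaks at or above the median score, 96.4% for as many top peaks as replicate 2 has, and between 39.4% (without replicate 2) and 68.5% (without replicate 1) when a replicate was left out. The ratio of X to autosomes, 0.68, stayed below 1 throughout: 0.778 in covered bases, 0.728 for the peaks at or above the median score, 0.750 in the series-level list, 0.567 in chromosome centres, 0.752 on arms and 0.611 without V. The log2 ratio of centres to arms passed 0.05 (exact p = 0.031, the smallest possible) for the peaks at or above the median score, 0.45, and in the series-level list, 0.26, and ranged from 0.25 without replicate 2 to 0.31 without replicate 1, where it also passed. It did not pass without replicate 2 (exact p = 0.094), nor when the centre was widened to the middle 50% of the chromosome, 0.33 (exact p = 0.062). For 5 autosomes alone, 0.35, the smallest possible p is 0.062. The cause of these moves was not tested. No paired analysis was possible because no values of the input samples were analysed here. The planned gene-level alternatives were not run, as no annotation of WS220 was used. Read depth is unknown, so whether depth limits the lists cannot be said.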

Other observations

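Some tests in this part were set beforehand: on the share of replicate 1 peaks found in replicate 2, on the share of series-level peaks inside replicate peaks, and on the scores of those outside. All others were chosen after the result was seen. The X ratios in the series-level list and among the peaks at or above the median score were planned as values. Their use here to weigh an explanation was chosen afterwards.

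The series-level peaks were also set out by class along the chromosomes. Peaks found in both replicates were denser in chromosome centres than on arms, 1.44-fold as a geometric mean and on 6 of 6 chromosomes. Peaks found in neither were denser in the centre on 1 of 6 chromosomes, III, with a mean ratio of 0.900. On V the ratios were 1.81 and 0.844, and on II 1.71 and 0.886. The classes are defined by overlap with replicate peaks that are themselves denser in centres, so a difference between them is built in: with the series-level list shifted by 10 to 50 kb and classed again, the difference in log2 ratio was 0.45 on average over 1000 shifts (0.13 to 0.73), against 0.68 observed. For the peaks found in both, the log2 ratio was 0.53 against 0.63 on average (0.34 to 0.86) after shifting, so their density in centres was within the range that is built in. For the peaks found in neither, the log2 ratio was -0.15, against 0.17 on average (0.12 to 0.23) after shifting, but that shifted class also holds sites that truly overlap replicate peaks. No difference in placement is therefore claimed.

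A few peaks at the score ceiling of a replicate had no counterpart in the other. There were 4 such peaks among the 110 of replicate 1 with a score of 3100 or more, and 6 among the 393 of replicate 2. The replicate 1 peaks were on I at 4685312 to 4698569, on I at 11763720 to 11772262, on II at 4571808 to 4587780 and on V at 17942055 to 17947164. The nearest replicate 2 peak was 14.6, 51.8, 7.17 and 3.37 kb away. All 10 contained series-level peaks, the best of which ranked at percentiles 92.2 to 99.6 of that list. The widest replicate 2 example, on V at 13381536 to 13397229, spanned 15.7 kb and held 7 series-level peaks.

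The share of peaks on X was compared between stronger and weaker peaks of each list. In the series-level list X held 13.2% of the peaks at or above the median score and 14.6% of those below (Fisher's exact test, p = 0.0079, adjusted over 3 lists 0.024). In the replicates the shares were 13.2% and 11.3% (Fisher's exact test, adjusted p = 0.24) and 13.9% and 12.62% (adjusted p = 0.27), neither of which passed, and the difference between lists was not tested. The top score decile of the series-level list had 10.8% of its peaks on X and the lowest 15.8%.

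Replicate 2 listed 1.43 times as many peaks as replicate 1. Cutting of the same bases into more peaks is argued against, since covered bases were 1.55 times as many. A more sensitive call of a common ranking in replicate 2 would leave the extra peaks weak, as they were, but 86.8% of replicate 1 peaks found in replicate 2 lay between the bounds of 70 and 90% set beforehand, so it stays open. In the top score quartile of replicate 1, 620 of 668 peaks were found in replicate 2. Sequencing depth and the composition of the embryo cultures were not tested, and no biological explanation was tested.

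The series-level list held 6.93 times as many peaks as replicate 1 and 4.85 times as many as replicate 2. Of the replicate 1 peaks 71.8%, and of the replicate 2 peaks 76.3%, overlapped several series-level peaks. Of the series-level peaks 74.6% overlapped a replicate peak, between the bounds of 50 and 80% set beforehand. In bases, 87.5% of the series-level coverage lay inside replicate peaks. Division is still argued against as the whole account of the peak number, since the 25.4% of peaks outside cannot be pieces of replicate peaks. By the bounds set beforehand the test was undecided, so this reading was made after the value was seen. The 4132 merged regions covered in either replicate held 3.34 series-level peaks each on average, so division may account for part. The peaks outside may be weaker sites that the replicate lists leave out. Their median score percentile differed by -29.2 points from that of the peaks inside, against -4.2 on average after shifting by 10 to 50 kb. The different caller versions named in the lists are confounded with the list.

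Peaks were less dense on X than on the autosomes as a whole. The lower density was also seen among weaker peaks, but a threshold that hides weaker X peaks cannot be excluded. The bounds for that explanation were set after the values were seen. The ratio in the series-level list, which holds weaker peaks, was 0.750, and below the median score there 0.793. These lie above the 0.649 and 0.711 of the replicates, so in peak numbers a threshold may account for part. In covered bases over all peaks no such rise was seen, with 0.771 in the series-level list and 0.769 and 0.786 in the replicates. Within the replicates the ratio was lower below the median score (0.593 and 0.672) than above it (0.706 and 0.750). The shares of peaks on X behind these ratios did not differ detectably (Fisher's exact test, adjusted p = 0.24 and 0.27). The series-level list also differs in caller version and peak width, so it is not the replicate lists at a lower threshold. A density that an autosome shares remains possible for whole chromosomes, where the ratio of X to V was between 0.959 and 1.21 over the 3 lists. In the centres it stays open: X was sparser than V there in replicate 1 (ratio 0.673, exact interval 0.522 to 0.864) and replicate 2 (0.805, 0.659 to 0.983), but not in the series-level list (1.03, 0.945 to 1.13). On arms X was denser than V in replicate 2 (1.295, 1.11 to 1.52) and in the series-level list (1.33, 1.24 to 1.43), and in replicate 1 the interval included 1 (1.18, 0.981 to 1.43), so the whole-chromosome ratios average a lower ratio in centres and a higher one on arms. Gene content of the chromosomes was not used here, and dosage compensation was not tested by any sample of the design.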
